A study of Mus musculus with 10 samples.

How the data were processed

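The series holds RNA sequencing of mouse placentas from wild-type animals and from animals lacking Tfeb, a transcription factor of lysosome and autophagy genes. Placentas were taken at embryonic day 9.5 (E9.5), with 3 wild-type and 3 Tfeb knockout (KO) libraries, and at E11.5, with 2 wild-type and 2 KO libraries. The labels describe total RNA from whole placentas of mice on a C57BL6 background, without saying how maternal decidua was separated, whether the libraries of a group came from different litters, or which part of Tfeb was removed. The p-values for single genes therefore measure the spread between these libraries only. Permutation tests, bootstrap intervals and Fisher's exact tests took genes as independent units, although genes vary together, and do not measure the spread between libraries.

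The deposited tables hold whole-number read counts per gene symbol, with a column per library and a table per stage. Per the submitters' processing notes, the authors used the mm10 genome, STAR 2.7.9a, Subread with featureCounts 2.0.1, and DESeq2. The notes give neither the roles nor the settings of these tools, nor whether counting used strand, and reads were not realigned. Without strand, reads from genes on opposite strands of the same bases cannot be told apart, and the treatment of reads that match several places is not stated. The column names of the E9.5 table carry another stage name than the labels, so its columns were matched to libraries by genotype and number.

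The libraries held 26983385 to 30632796 counts, over 54096 listed gene symbols. At this depth the spread between libraries, not counting error, set the precision for all but the lowest genes, and intervals given for ratios of counts cover counting error only. The most abundant gene, mt-Co1, took 1.24% to 2.76% of the counts.

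Each stage was tested on its own libraries with edgeR 4.0.16 in R 4.3.3, using its filter on low counts, TMM scaling, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Every adjusted p for a gene comes from this edgeR test unless another tool is named. The difference between the stages in the KO effect and the comparison of the stages in wild type came from a fit of all 10 libraries. Stage and deposited table are the same split, so that a difference between tables cannot be separated from stage in the latter comparison. Expression levels are CPM, the counts relative to the TMM-scaled library size, given as mean ± SD over the libraries of a group.

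Lists of marker and pathway genes, 44 in all, were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The camera test with an estimated correlation and the fry test were run beside it. With an estimated correlation, camera has only the degrees of freedom left by the few libraries, so a call lost there also reflects low power. Where the estimate lay above 0.01, the preset test took the genes as closer to independent than estimated. The E9.5 comparison had a single measured neutrophil gene, which left 43 lists. A list score is the mean log2 CPM of its members in a library. The lists, the tests, the alternatives to be tried and the rule for naming genes were set before the data were examined.

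The rule named Tfeb and its relatives, 11 genes tied to placental development, and, per KO comparison, up to 6 genes each way with the largest fold changes. Those had to pass the threshold, to average at least 5 CPM and to separate every KO from every wild-type library, and unnamed gene models were passed over. It also named up to 4 members of each list that passed, or the most abundant members where none did, 6 genes for the difference between stages, and the 5 largest changes each way for the stages in wild type. Genes named outside the rule are said to have been chosen after their values were seen.

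The edgeR analysis was tested on simulated counts drawn from each gene's mean over all libraries of a comparison and the real library sizes, with 200 genes changed. A further set of genes, lowered 2-fold for a test of the lists, is not counted here. Each gene was drawn independently, whereas real genes vary together. The counts of unchanged genes called therefore do not show the error rate in the real data. At E9.5, where 15871 genes were tested, it recovered 10.4% of the genes changed 2-fold, 79.1% of those changed 4-fold and 95.5% of those changed 16-fold, with 10 unchanged genes called. At E11.5, with 16213 genes, the shares were 40.3%, 97.0% and 100%, with 27 unchanged genes called. For the difference between stages, with 17524 genes, they were 1.49%, 41.8% and 90.9%, with 3 called.

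Alternatives covered other scalings, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, a shared fit, a replicate block, a fold change limit and leaving out each library. A covariate for decidual RNA, and fits without a pair of E9.5 KO libraries low in it, were added after the data were seen. Positions come from the GENCODE M21 annotation of GRCm38, the build the submitters name mm10. Of 238 named genes, 54 share exon bases with another annotated gene and 38 have at least 200 bases at 95% identity or more in another gene's transcripts. The values of these genes, which include Tgfa, Ccnd1, Ramp3, Rhpn2, Cts3, Psg27 and Slc7a11, are uncertain to that extent, whether or not this is said beside them.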

Results

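Gene expression was measured by RNA sequencing in whole placentas of wild-type and Tfeb KO mice at E9.5 and at E11.5. TFEB is a transcription factor that drives genes of lysosomes and autophagy, and the series title ties it to trophoblast syncytialization, the fusion of trophoblast cells into the multinucleate layers that line the placental exchange surface. In the mouse these are 2 layers of the labyrinth, SynT-I next to maternal blood and SynT-II next to fetal vessels. The E9.5 set comprised 3 libraries per genotype and the E11.5 set 2 per genotype, each with 26983385 to 30632796 counts.

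Tfeb itself was low in every KO library. Its counts were 1632, 1088 and 1455 in the wild-type libraries at E9.5 and 55, 55 and 46 in the KO libraries, and at E11.5 they were 4212 and 3061 in wild type and 124 and 146 in KO. This amounted to 49.0 ± 14.0 against 1.78 ± 0.335 CPM at E9.5 (SD, n = 3 per group; log2 fold change -4.79, SE 0.29, adjusted p = 0.0064) and to 120 ± 23.7 against 5.04 ± 0.653 CPM at E11.5 (n = 2 per group; -4.58, SE 0.27, adjusted p = 1.4e-09). Tfeb lies on chromosome 17 of GRCm38, from 47737030 to 47792419 on the plus strand, with 35 distinct annotated exons, and the counts cover the whole gene. Among its relatives, Tfe3 had log2 fold changes of -0.18 and -0.14 at E9.5 and E11.5 and Mitf of -0.91 and 1.37, none of which passed. Tfec had a value of 0.36 at E9.5, which did not pass, and was lower in KO at E11.5 (-2.67, SE 0.61, adjusted p = 0.0044), on 59 counts in wild type and 8 in KO.

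The first question was which genes differ between KO and wild-type placentas at E9.5, when the labyrinth starts to form. A small set of genes was far lower in the KO placentas, among them 4 of 10 SynT-I genes. Syna, which encodes the retrovirus-derived fusion protein syncytin-A of SynT-I, went from 29.7 ± 17.9 to 0.901 ± 0.287 CPM (n = 3 per group), a 33.0-fold fall (log2 fold change -5.05, SE 0.54, adjusted p = 0.022). Dio3, which encodes a deiodinase that inactivates thyroid hormone, went from 61.8 ± 30.0 to 1.13 ± 0.21 CPM (-5.77, SE 0.42, adjusted p = 0.0064). Genes that mark SynT-II or labyrinth progenitors did not pass in either direction.

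In all, 38 of 15871 genes tested at E9.5 were lower in KO and 0 were higher by edgeR. At an unadjusted p under 0.05 the counts were 729 lower and 224 higher, while DESeq2 called 6 genes higher and limma-voom 0. Among named genes that averaged at least 5 CPM and separated the genotypes, the largest falls were those of Dio3, Syna, Tfeb, Snap91, Tgfa and Rassf6. Snap91, a clathrin assembly protein of endocytosis, went from 25.9 ± 6.61 to 1.11 ± 0.271 CPM (log2 fold change -4.54, SE 0.30, adjusted p = 0.0064). Tgfa, a ligand of the EGF receptor, went from 17.0 ± 5.39 to 0.933 ± 0.29 CPM (-4.18, SE 0.36, adjusted p = 0.0088). Rassf6, of the RAS association domain family, went from 20.2 ± 0.779 to 1.49 ± 0.404 CPM (-3.76, SE 0.26, adjusted p = 0.0064). In GRCm38, Syna is a gene of 1 exon on chromosome 5 (134558146 to 134560171, minus strand), Dio3 lies on chromosome 12 (110279068 to 110281097), Snap91 on chromosome 9 (86765923 to 86880654) and Tgfa on chromosome 6 (86195223 to 86275719). A stretch of 310 bases of Syna is shared with the opposite-strand gene model Gm42884, so reads there cannot be assigned without strand, and Tgfa likewise shares exon bases with the opposite-strand gene model Gm43917.

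**Figure D1:**
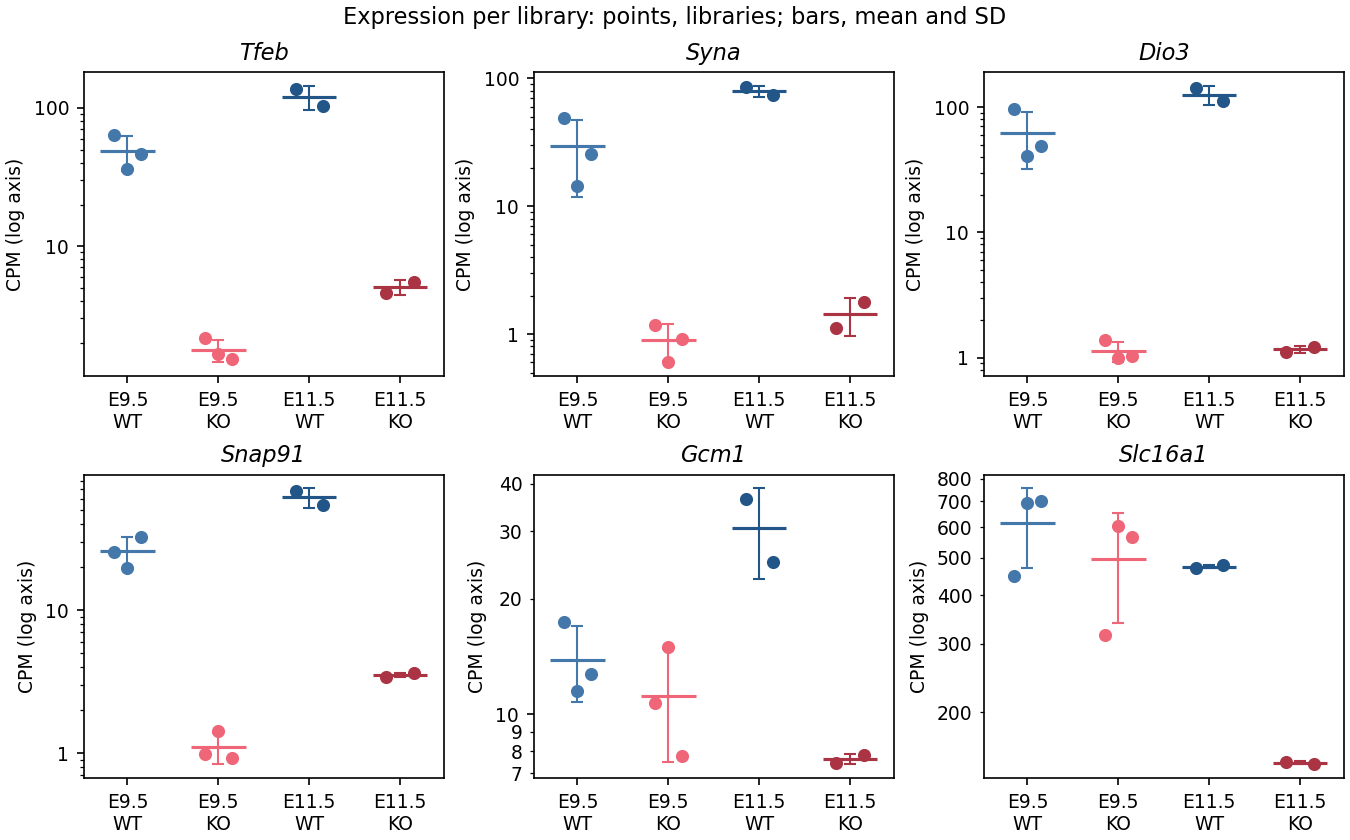
Expression of 6 genes in each library, in CPM on a log axis, with points for libraries and bars for the mean and SD of each group. Tfeb, Syna, Dio3 and Snap91 were low in all KO libraries at E9.5 and E11.5, whereas Gcm1 and Slc16a1 passed the test for lower expression at E11.5 and not at E9.5. Neither Gcm1 nor Slc16a1 passed the test of the difference between the stages in the KO effect.

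Of the 10 SynT-I genes, 4 fell at E9.5, namely Syna, Snap91, Tgfa and the ephrin receptor gene Epha4 (log2 fold change -1.57, SE 0.19, adjusted p = 0.035), and 5 passed when adjusted over the list alone. The median over the list was -0.82 and camera called it lower (adjusted p = 3.0e-09), with adjusted p = 0.11 with an estimated correlation and adjusted p = 8.6e-04 by fry. The estimated correlation was -0.049, below the preset 0.01, so correlation between genes did not cause the loss of that call. The SynT-I score was 5.51, 5.30 and 5.55 in the wild-type libraries and 3.79, 3.66 and 3.67 in the KO libraries. None of 8 measured SynT-II genes passed by edgeR, over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 of them. Their median was -0.16, and camera gave adjusted p = 0.087, or 0.47 as adjusted p with an estimated correlation. The SynT-II regulator Gcm1 had a log2 fold change of -0.31 (SE 0.29), Vegfa of -0.21, the lactate transporter genes Slc16a1 and Slc16a3 of -0.31 and -0.08, and Ly6e, the receptor for syncytin-A, of -1.64 (SE 0.73, adjusted p = 0.85). Synb, the SynT-II syncytin gene, had only 1 to 5 counts per library and was not tested at E9.5. The 10 labyrinth progenitor genes gave 0 calls by edgeR (0 adjusted over the list alone, 1 higher at an unadjusted p under 0.05, and 0 by DESeq2) and a median of 0.28, which camera called higher (adjusted p = 0.029), with adjusted p = 0.51 with an estimated correlation. Pparg, Cdx2, Tpbpa and Ctsq had log2 fold changes of -0.51, -0.16, -0.62 and -0.59, none of which passed.

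Among 28 regulators of syncytialization and the labyrinth, 2 passed, Tfeb and Syna (3 adjusted over the list alone), and camera called the list lower (adjusted p = 0.0055, and adjusted p = 0.47 with an estimated correlation). Of 33 nutrient transporter genes, only Fabp5, a fatty acid binding protein gene, passed (log2 fold change -1.74, SE 0.22, adjusted p = 0.036), with 2 lower when adjusted over the list alone. Camera called that list lower (adjusted p = 0.0039, and adjusted p = 0.38 with an estimated correlation). None of 44 lysosomal genes of the CLEAR network, the known targets of TFEB, passed over all genes by edgeR, while 2 were lower when adjusted over the list alone, 5 at an unadjusted p under 0.05 and 2 by DESeq2. Their median was -0.27, the abundant members Psap and Ctsb had -0.72 and -0.43, and camera called the list lower (adjusted p = 1.4e-08, and adjusted p = 0.47 with an estimated correlation). The CLEAR median was 0.01 without the E9.5 KO libraries 2 and 3.

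Interferon response genes had the strongest camera call at E9.5. None of 30 passed over all genes by edgeR, whereas 8 were lower when adjusted over the list alone, 16 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom, the first being Oasl2 (log2 fold change -2.27, SE 0.34, adjusted p = 0.007 over the list alone). In 29 the fold change was negative, and in 15 the KO and wild-type libraries did not overlap, all with KO lower, where chance gives 10% over both directions. The median was -1.22 and the camera adjusted p was 1.3e-16, with adjusted p = 0.38 with an estimated correlation, and the abundant members H2-D1 and H2-K1 had log2 fold changes of -0.70 and -0.78. Genes of mitosis had 0 calls among 25 by edgeR (0 adjusted over the list alone, and 3 higher at an unadjusted p under 0.05) and a median of 0.29, with Top2a at 0.22 and Mki67 at 0.23, and the median was 0.15 with the decidual score as a covariate among these libraries. Camera called this list higher (adjusted p = 1.3e-06, and adjusted p = 0.47 with an estimated correlation).

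Maternal and junctional zone markers varied between the E9.5 libraries. The decidual stroma score was 4.26, 4.33 and 4.71 in wild type and 4.10, 2.29 and 2.72 in KO, and Prl8a2, a decidual prolactin, had 8025, 8358 and 16778 counts against 5584, 7 and 72. The spongiotrophoblast score in the KO libraries was 3.50, 0.28 and 1.98, against 3.18 to 3.48 in wild type. None of 18 decidual, 13 uterine natural killer cell and 16 spongiotrophoblast genes passed by edgeR, over all genes or adjusted over the list alone, while 4, 7 and 1 were lower at an unadjusted p under 0.05 and 1, 2 and 0 by DESeq2. Their medians were -0.58, -1.87 and -0.79, and camera called each list lower (adjusted p = 2.0e-04, 1.8e-09 and 1.5e-05), with adjusted p = 0.47 with an estimated correlation in each. The CLEAR, interferon and decidual lists thus had negative medians in the same comparison. The interferon score did not follow the decidual score among the KO libraries, however. It was 0.88 in KO library 1 and 0.98 and 1.08 in KO libraries 2 and 3. In wild-type libraries 1, 2 and 3 it was 1.75, 2.53 and 2.76, in the same order as their decidual scores. With 3 libraries per genotype, a decidual part in the interferon values stays open. Without KO libraries 2 and 3 the interferon median was -1.62.

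The E9.5 count depended on single libraries. It was 19, 13 and 15 without wild-type libraries 1, 2 and 3, and 325, 13 and 0 without KO libraries 1, 2 and 3, and the SynT-I count of 4 became 2 without wild-type library 3, 2 without KO library 2 and 0 without KO library 3. All 38 genes kept a negative fold change in each of these fits. Without KO library 3 their median was -3.82, against -3.73 with all libraries, and the median SE was 0.41 against 0.32. Precision fell there and not the size of the effect. With the decidual score as a covariate among the E9.5 libraries edgeR called 0 genes (408 lower and 236 higher at an unadjusted p under 0.05), although all 38 kept a negative fold change there, with a median of -3.40 against -3.73 and a median SE of 0.57 against 0.32, while with the covariate in a fit of all 10 libraries 31 genes passed, 3 of them SynT-I members.

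At E11.5 the question was the same, and the KO placentas differed far more from wild type. Lower genes included 8 of 10 SynT-I, 6 of 9 SynT-II, 10 of 11 primitive erythroid, 9 of 12 definitive erythroid and 17 of 35 nutrient transporter genes, and 9 of 18 decidual genes were higher and 3 lower. Each of these lists was called by camera, with adjusted p = 0.54 with an estimated correlation. Syna fell to 1.44 ± 0.469 from 79.2 ± 7.5 CPM (n = 2 per group; log2 fold change -5.78, SE 0.31, adjusted p = 4.2e-10), and Gcm1, the transcription factor that directs SynT-II formation, to 7.63 ± 0.242 from 30.7 ± 8.14 CPM (-2.01, SE 0.27, adjusted p = 2.7e-05). Hemgn, an erythroid nuclear protein gene, fell to 2.46 ± 0.405 from 101 ± 14.8 CPM (-5.36, SE 0.28, adjusted p = 4.2e-10). Cxcl14, a chemokine gene, rose to 11.2 ± 0.557 from 0.516 ± 0.131 CPM (4.43, SE 0.36, adjusted p = 6.9e-08).

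Of 16213 genes tested at E11.5, 1649 were lower and 932 higher in KO. Among named genes that averaged at least 5 CPM and separated the genotypes, the largest falls were those of C1ql2, a secreted C1q-like protein gene, the solute carrier genes Slc28a3, Slc34a2, Slc26a7 and Slc1a1, and Dio3. C1ql2 had 726 counts over the wild-type libraries and 1 over the KO libraries, a ratio of 645 (95% interval 115 to 25500), and Slc28a3 had 625 and 1, a ratio of 556 (99.3 to 22000). Slc34a2, a phosphate transporter gene, had a log2 fold change of -7.72 (SE 0.46, adjusted p = 6.8e-08), Slc26a7 of -7.26 (SE 0.43, adjusted p = 1.3e-09) and Slc1a1 of -7.22 (SE 0.49, adjusted p = 5.8e-09). Slc1a1 and Slc28a3 share exon bases with opposite-strand genes and are uncertain in that respect. Dio3 fell to 1.16 ± 0.0695 from 126 ± 21.4 CPM (-6.77, SE 0.31, adjusted p = 8.6e-11). Within the same limits the largest rises after Cxcl14 were those of Mustn1 (3.42), Tdo2 (3.37), Fbln5 (3.33), Ramp3 (3.20) and Trem2 (3.19), with adjusted p from 1.5e-07 to 0.0027. C1ql2 lies on chromosome 1 (120340582 to 120343174), Slc34a2 on chromosome 5 (53038081 to 53071664), Gcm1 on chromosome 9 (78051924 to 78065624) and Cxcl14 on chromosome 13 (56288643 to 56296551).

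**Figure D2:**
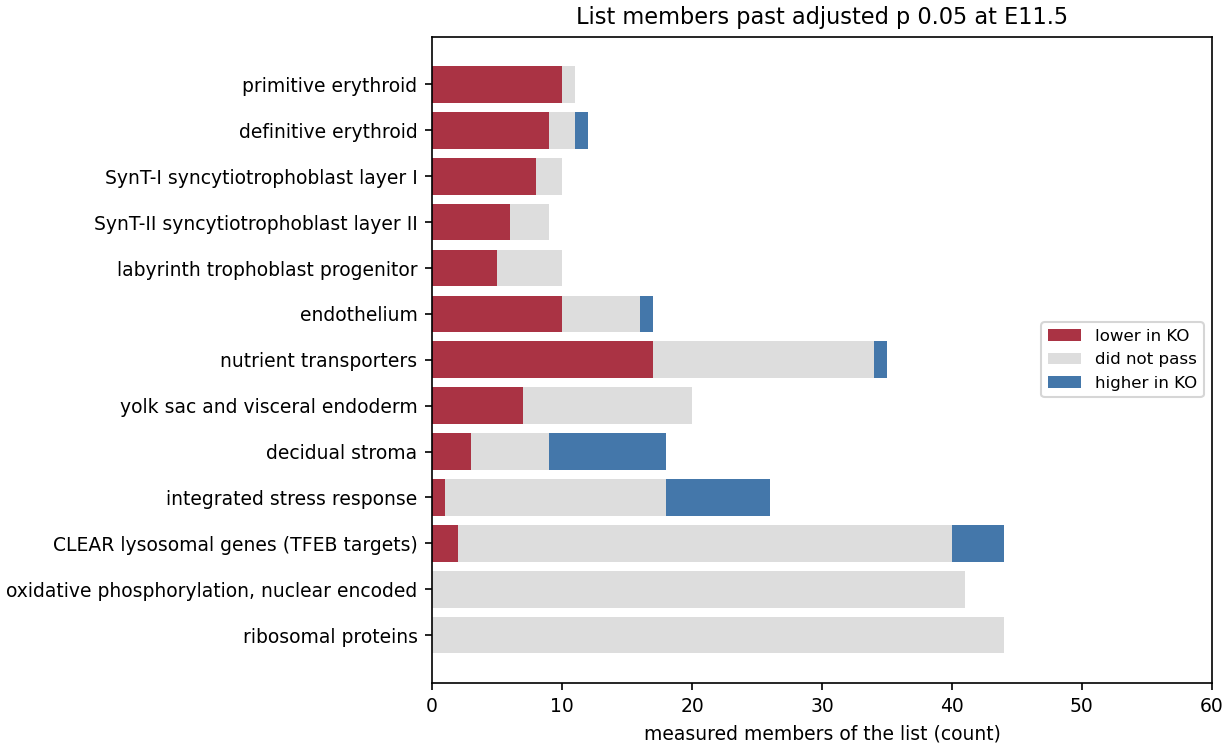
Number of measured members of 13 gene lists that were lower in KO, higher in KO or did not pass at E11.5, as stacked bars. The erythroid lists had 10 of 11 and 9 of 12 members lower, and 9 of 18 decidual genes were higher.

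Of 10 SynT-I genes, 8 fell at E11.5 (9 adjusted over the list alone), among them Tgfa (log2 fold change -4.92), Snap91 (-4.12) and the transferrin receptor gene Tfrc (-3.27), with a median of -2.45. Of 9 SynT-II genes, 6 fell (7 lower and 1 higher adjusted over the list alone), among them Gcm1, Ly6e (-2.99, SE 0.45, adjusted p = 0.008), the glucagon receptor gene Gcgr (-2.09) and Slc16a3 (-1.03), with a median of -1.03. Camera called these lists lower (adjusted p = 4.6e-08 and 0.0028), with adjusted p = 0.54 with an estimated correlation for each. Slc16a1, the lactate transporter gene of SynT-I, fell to 148 ± 1.55 from 475 ± 3.82 CPM (-1.68, SE 0.22, adjusted p = 2.1e-05), and Vegfa fell as well (-0.70, SE 0.23, adjusted p = 0.046). Synb had 22 and 15 counts in wild type and 7 and 2 in KO (-1.84, SE 0.62, adjusted p = 0.049). This value is uncertain, since 3017 of its 4055 bases are identical in the gene model Gm27179. Of 29 regulators 17 fell (18 adjusted over the list alone; camera adjusted p = 3.4e-08, and adjusted p = 0.54 with an estimated correlation), among them the connexin gene Gjb2 (-3.75) and Ovol2 (-2.31). Of 10 labyrinth progenitor genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.54 with an estimated correlation), among them Cdh1 (-1.61) and Met (-1.88). Cdx2, a trophoblast stem cell gene, rose (1.29, SE 0.23, adjusted p = 6.7e-04), while Pparg (0.39), Tpbpa (1.41) and Ctsq (0.25) did not pass.

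Red blood cell genes showed the lowest medians of the lists at E11.5. Of 11 primitive erythroid genes 10 fell (10 adjusted over the list alone), among them Rhag (log2 fold change -5.40), Tal1 (-3.96), Klf1 (-3.94) and Gata1 (-2.49), with a median of -4.08. Of 12 definitive erythroid genes 9 fell and 1 rose (10 lower and 1 higher adjusted over the list alone), with a median of -3.86 and with Hemgn, Sptb (-5.14), Epb42 (-5.09) and Hbb-bt (-3.70) among those that fell. Hbb-bt shares a stretch of 323 identical bases with Hbb-bs and is uncertain on its own. The member that rose was Car2 (SE 0.28, adjusted p = 0.0014), a carbonic anhydrase gene named after its value was seen. Camera called both lists lower (adjusted p = 1.5e-10 and 1.9e-09), with adjusted p = 0.54 with an estimated correlation. Of 17 endothelial genes 10 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -1.02, among them Tek (-2.09) and Lyve1 (-1.77). The endothelial gene that rose, named after its value was seen, was Flt4 (1.32), and camera called the list lower (adjusted p = 0.009, and adjusted p = 0.63 with an estimated correlation). Of 20 yolk sac and visceral endoderm genes 7 fell (13 adjusted over the list alone; camera adjusted p = 7.6e-09, and adjusted p = 0.54 with an estimated correlation), among them Fgg (-3.31), Cubn (-2.93) and Hnf4a (-2.15). The yolk sac score was 4.95 and 3.72 in wild type and 2.42 and 1.58 in KO, and at E9.5 none of 19 such genes passed by edgeR (3 were higher at an unadjusted p under 0.05). Camera called the list higher at E9.5 (median 0.50, adjusted p = 0.015, and adjusted p = 0.66 with an estimated correlation).

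Of 35 nutrient transporter genes, 17 fell and 1 rose at E11.5 (23 and 2 adjusted over the list alone), with a median of -0.91. Those that fell included Tfrc, the zinc and iron transporter gene Slc39a8 (log2 fold change -3.29) and the folate receptor gene Folr1 (-3.76), and Fabp4 rose (2.54). Camera called the list lower (adjusted p = 3.4e-07, and adjusted p = 0.54 with an estimated correlation). Genes of the integrated stress response, which amino acid shortage and other stresses switch on, rose in 8 of 26 cases and fell in 1 (9 and 1 adjusted over the list alone), with Slc7a11 at 2.64, Gdf15 at 2.69 and Trib3 at 1.66 and with Atf3 at -1.95. Camera called that list higher (adjusted p = 0.001, and adjusted p = 0.54 with an estimated correlation). Of 44 CLEAR genes 4 rose and 2 fell (4 and 2 adjusted over the list alone), with Naglu at 1.56 and Ctsl at 1.24, and with Smpd1, an acid sphingomyelinase gene, at -2.60 and Hexb at -0.96. Camera did not call the list (adjusted p = 0.32). Interferon response genes split evenly, with 8 of 34 higher and 8 lower (10 and 9 adjusted over the list alone), such as Ifi44 (2.33), H2-D1 (1.33), Oasl2 (-1.78) and Isg15 (-1.61), and camera did not call the list (adjusted p = 0.32). None of 41 nuclear genes of oxidative phosphorylation and none of 44 ribosomal protein genes passed at E11.5 by edgeR, over all genes or adjusted over the list alone, with 1 lower and 3 higher at an unadjusted p under 0.05 and 0 by DESeq2. Camera nonetheless called the ribosomal protein list higher (adjusted p = 4.3e-04, and adjusted p = 0.63 with an estimated correlation), with 44 positive fold changes and a median of 0.32.

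Some genes of the maternal decidua and of the junctional zone rose at E11.5. The decidual stroma score was 2.50 and 3.53 in wild type and 4.60 and 4.66 in KO, and Prl8a2 had 22 and 3283 counts against 16391 and 16438. Of 18 decidual genes 9 rose and 3 fell (9 and 4 adjusted over the list alone), with Dcn (log2 fold change 1.97), Hand2 (1.88), Cryab (1.65) and Hoxa10 (1.87) among those that rose. The 3 that fell were Wnt4, Alpl and Igfbp4, named after their values were seen. Of 22 spongiotrophoblast genes 3 rose (4 adjusted over the list alone), among them Prl5a1 (2.76) and Ascl2 (0.79), and of 13 uterine natural killer cell genes 2 rose (3 adjusted over the list alone), Klrd1 (2.95) and Il2rb (0.90). Camera called the decidual, spongiotrophoblast and natural killer lists higher (adjusted p = 3.1e-04, 1.8e-07 and 1.6e-07), with adjusted p = 0.54 with an estimated correlation in each. The rises of Tdo2, Ramp3, Fbln5 and Cxcl14 came in the same libraries as the high decidual scores.

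With 2 libraries per group, leaving out a library left a lone sample in an arm, assumed to vary like the others. The E11.5 count of 2581 became 4468 without wild-type library 2, 708 without KO library 1 and 771 without KO library 2, and the counts for SynT-II (6), nutrient transporters (17) and endothelium (10) became 2, 11 and 1 without KO library 1 and 2, 9 and 2 without KO library 2, with SynT-II at 3 without wild-type library 1. In a fit of all 10 libraries 1023 genes passed, with 7 SynT-I, 7 definitive and 9 primitive erythroid, 12 nutrient transporter, 4 endothelial, 1 SynT-II and 5 decidual members, and with the decidual score as a covariate in that fit 151 passed, all of them lower, with 5, 7, 4, 5, 1, 0 and 0 such members by edgeR. The decidual members make up the score, so the loss of their calls was built into that fit.

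**Figure D3:**
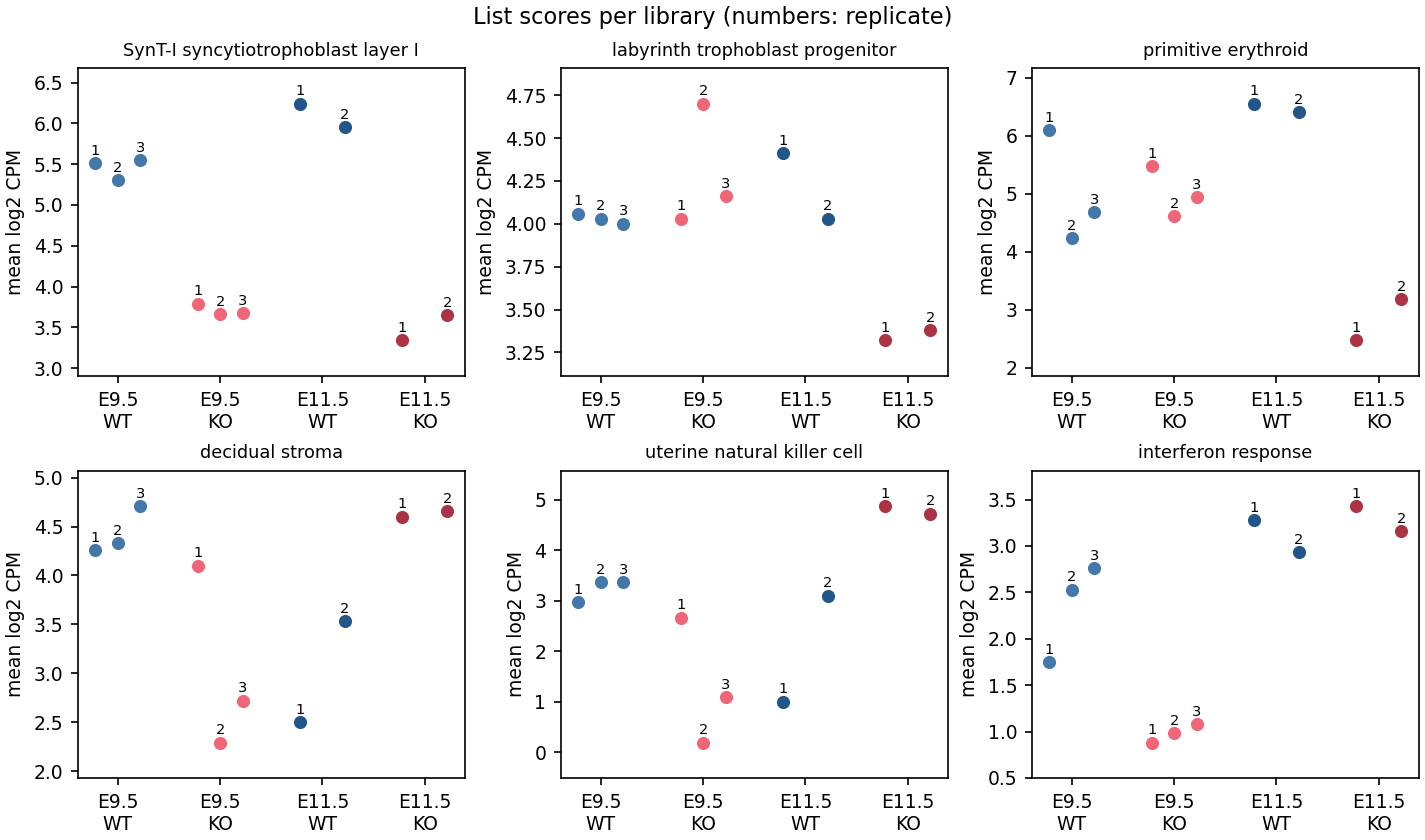
Score of gene lists in each library, as the mean log2 CPM of the members, with points for libraries grouped by stage and genotype. The SynT-I score was 3.34 to 3.79 in all KO libraries and 5.30 to 6.24 in all wild-type libraries, while the decidual score varied within groups.

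The next question was whether the KO effect itself differed between E9.5 and E11.5. Most genes lower at E9.5 were also lower at E11.5, whereas erythroid genes were lower in KO at E11.5 and had list medians of -0.15 and -0.18 at E9.5, with none passing. Of the 38 genes lower at E9.5, 37 were lower at E11.5 as well, where independent lists of that size among 15034 genes tested at each stage would share 3.68 (Fisher's exact test, p = 6.95e-37). The exception was Fabp5, at -1.74 at E9.5 and -0.28 at E11.5, a difference that passed (1.48, adjusted p = 0.037). Spta1, which encodes erythroid spectrin, had 29.2 ± 10.5 and 26.9 ± 7.22 CPM in wild type and KO at E9.5 (n = 3) and 54.4 ± 2.36 and 1.44 ± 0.726 at E11.5 (n = 2).

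**Figure D4:**
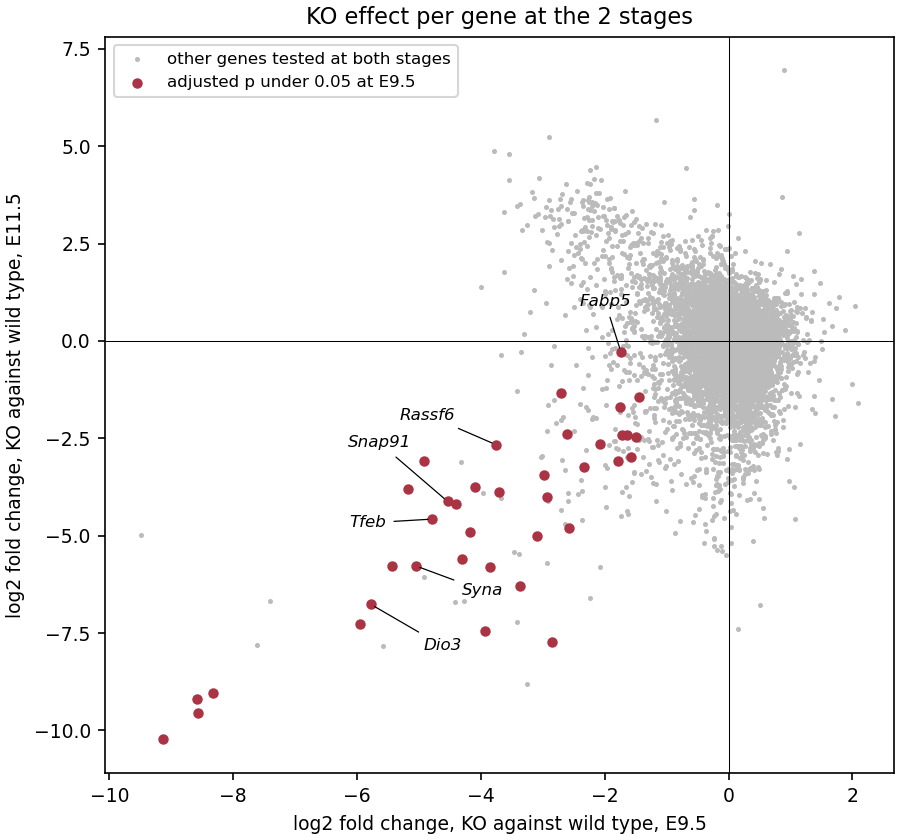
Log2 fold change of KO against wild type at E9.5 (horizontal axis) and at E11.5 (vertical axis) for each gene tested at both stages, with the genes that passed at E9.5 in red. Of the 38 red points, 37 also passed at E11.5 with a negative value, and Fabp5 did not.

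The test of the difference called 430 of 17524 genes, 178 with a more positive and 252 with a more negative KO effect at E11.5. The smallest adjusted p among named genes was that of Sel1l3 (log2 difference -4.37, SE 0.38, adjusted p = 0.0074), which went from 30.6 ± 8.00 to 1.83 ± 0.51 CPM at E11.5 and had 7.07 ± 1.35 and 8.74 ± 0.72 CPM at E9.5. It was followed by Spta1 (-5.12), Stard8 (-3.65), Rhpn2 (-3.21), Slc22a23 (-2.26) and the cyclin D1 gene Ccnd1 (-2.68), each with an adjusted p of 0.012. Among erythroid genes, 4 of 11 primitive and 7 of 12 definitive ones had a more negative effect at E11.5 (10 and 7 adjusted over the list alone), and 1 definitive gene had a more positive effect adjusted over the list alone. Camera called these lists lower (adjusted p = 5.1e-09 and 1.6e-07), with adjusted p = 0.27 with an estimated correlation. Of 10 SynT-I genes 2 had a more negative effect at E11.5, Tfrc (-2.22) and Epha4 (-1.40), and 3 did when adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.27 with an estimated correlation). Of 9 SynT-II genes 0 differed over all genes by edgeR, and 1 had a more negative effect when adjusted over the list alone. Camera did not call the SynT-II list (adjusted p = 0.13, and adjusted p = 0.43 with an estimated correlation). Gcm1, Ly6e, Slc16a1, Slc16a3 and Vegfa did not pass for the difference, so a later onset in SynT-II was not shown. Of 34 interferon genes 6 had a more positive effect (11 adjusted over the list alone), and of 18 decidual genes 6 had a more positive and 1 a more negative effect (10 and 3 adjusted over the list alone), in the same comparison. None of 44 CLEAR genes differed over all genes by edgeR, with 3 more positive and 1 more negative when adjusted over the list alone, 13 and 1 at an unadjusted p under 0.05, and 4 and 1 by DESeq2. Camera called the interferon, decidual and CLEAR lists more positive (adjusted p = 4.0e-08, 2.0e-04 and 2.5e-04), with adjusted p = 0.27, 0.27 and 0.42 with an estimated correlation.

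Single libraries decided the count of 430, which was 55, 29, 1710, 256 and 40 without E9.5 wild-type libraries 2 and 3 and KO libraries 1, 2 and 3, and 2, 0 and 0 without E11.5 wild-type library 1 and KO libraries 1 and 2. The 37 genes lower at both stages became 17, 13 and 15 without E9.5 wild-type libraries 1, 2 and 3 and 91, 13 and 0 without E9.5 KO libraries 1, 2 and 3, and with the decidual score as a covariate edgeR called 0 genes for the difference, against 173 with a more positive and 600 with a more negative effect at an unadjusted p under 0.05.

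The comparison of wild-type placentas at E11.5 and E9.5 gives the developmental background of these genes, with the deposited table changing along with the stage. At E11.5, 13 of 22 spongiotrophoblast and 7 of 11 macrophage genes were higher and 4 of 11 steroid synthesis genes were lower. Camera called these lists, with adjusted p = 0.61, 0.61 and 0.68 with an estimated correlation. Tfeb rose with stage (log2 fold change 1.36, SE 0.25, adjusted p = 0.0099), and so did Gcm1 (1.22, adjusted p = 0.028) and the SynT-I genes Syna (1.49), Tgfa (1.43), Stra6 (1.39) and Snap91 (1.31). Of 17524 genes, 1418 were higher and 731 lower at E11.5.

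Among named genes that averaged at least 5 CPM and separated the stages, the largest rises were those of Ceacam14 and Ceacam12, spongiotrophoblast genes with 11235 and 5070 counts at E11.5 and 2 and 1 at E9.5, followed by Cts3 (log2 fold change 10.34), Psg25 (10.25) and Psg27 (10.15). As a ratio of E9.5 to E11.5 this was 0.000119 for Ceacam14 (95% interval 0.0000144 to 0.000428). The largest falls were those of Cts7 (-8.04), Pfpl (-7.89), Ly6g6g (-7.17), Igfbpl1 (-7.01) and Prl3d3 (-6.96), a placental lactogen gene with near-identical copies, so that its own value is uncertain. Of 10 SynT-I genes 4 rose (4 adjusted over the list alone), with adjusted p = 0.13 by camera. Of 22 spongiotrophoblast genes 13 rose and 1 fell (14 and 3 adjusted over the list alone), and of 11 macrophage genes 7 rose (8 adjusted over the list alone), among them C1qa (4.37) and Cx3cr1 (4.68). Camera called the latter lists higher (adjusted p = 5.9e-05 and 1.2e-05), with adjusted p = 0.61 with an estimated correlation. Of 35 nutrient transporter genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), among them Cd36 (4.16), and the gene that fell was Slc2a3 (-1.98). Of 44 CLEAR genes 8 rose and 2 fell (11 and 3 adjusted over the list alone), among them Smpd1 (2.11) and Hexb (1.43), and camera called the last 2 lists higher (adjusted p = 0.036 and 0.048), with adjusted p = 0.61 and 0.73 with an estimated correlation. Of 11 steroidogenesis genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), with Cyp11a1 at -4.38 and Hsd3b6 at -4.22, and camera called the list lower (adjusted p = 0.019, and adjusted p = 0.68 with an estimated correlation). Parietal and other giant cell genes, with 4 of 14 lower and 2 higher (6 and 2 adjusted over the list alone), and decidual genes, with 3 of 18 lower and 3 higher (9 and 3 adjusted over the list alone), had medians of -1.29 and -1.24 in the same comparison. Camera called both lists lower (adjusted p = 0.019 and 0.0098), with adjusted p = 0.68 and 0.61 with an estimated correlation. The giant cell score was 8.07, 8.23 and 8.18 in the E9.5 and 5.58 and 7.63 in the E11.5 wild-type libraries, and the steroidogenesis score was 6.37, 6.42 and 6.15 against 4.29 and 4.94.

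The wild-type stage count of 2149 was 3310, 623 and 880 without E9.5 wild-type libraries 1, 2 and 3, 4006 without E9.5 KO library 1, which enters the shared spread, and 310 and 995 without E11.5 wild-type libraries 1 and 2. Without E11.5 wild-type library 1, Tfeb, Gcm1 and the 4 SynT-I genes no longer passed, and DESeq2 called 3306 genes in all.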

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

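Apart from the share of all differing genes that follow the decidual score, the tests on composition and blood described here were chosen after the results were seen, as was the decidual covariate. Of the genes named for a KO comparison, 45 had a KO effect that differed between E9.5 and E11.5 by a test of the difference itself, 33 with a more negative and 12 with a more positive effect at E11.5. Among those with the largest changes or the smallest p, the log2 difference for Slc28a3 was -5.55 (SE 1.25, adjusted p = 0.0499), with log2 fold changes of -3.26 at E9.5 and -8.81 at E11.5, on 1 count in KO at E11.5. For Spta1 it was -5.12 (SE 0.55; -0.12 at E9.5 and -5.26 at E11.5), for Slc34a2 -4.84 (SE 0.66; -2.85 and -7.72), for Sel1l3 -4.37 (SE 0.38; 0.30 and -4.09), for Slc1a1 -3.78 (SE 0.84; -3.41 and -7.22) and for Stard8 -3.65 (SE 0.40; -0.22 and -3.89). For Rhpn2 the log2 difference was -3.21 (SE 0.36; -0.13 and -3.36), for Ccnd1 -2.68 (SE 0.31; -0.12 and -2.82) and for Slc22a23 -2.26 (SE 0.26; -0.88 and -3.16). Effects were more positive at E11.5 for Tdo2 with 3.96 (SE 0.73; -0.56 and 3.37), Fbln5 with 4.93 (SE 0.85; -1.57 and 3.33), Cxcl14 with 5.15 (SE 0.82; -0.69 and 4.43) and Ramp3 with 5.25 (SE 1.1; -2.02 and 3.20).

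The other differing genes were members of the gene lists, with these log2 differences. Erythroid genes gave -5.52 (Sptb), -5.27 (Rhag), -5.15 (Hemgn), -4.84 (Epb42), -4.11 (Tal1), -3.19 (Hbb-bt) and -2.32 (Gata1). Trophoblast, endothelial and transporter genes gave -3.32 (Slc39a8), -2.80 (Zic3), -2.22 (Tfrc), -2.18 (Met), -1.95 (Tek), -1.72 (Ddah1), -1.61 (Itga4), -1.40 (Epha4) and 1.48 (Fabp5). Yolk sac genes gave -3.70 (Cubn) and -2.89 (Hnf4a), and signalling, imprinted, neural and mitosis genes gave -3.90 (Stmn2), -2.39 (Id1), -2.36 (Mest), -2.23 (Id3), -2.04 (Rspo3), -1.97 (Pdgfb) and -1.25 (Kif23). More positive effects at E11.5 were those of Pfkp (1.41), H2-D1 (2.05), the decidual genes Dcn (2.40) and Hoxa10 (2.74), Egr1 (2.48), Adm (3.34) and Slc7a11 (4.53).

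An unequal share of maternal decidua between libraries may account for many of the more positive effects, since the mean decidual score was 4.44 in wild type and 3.03 in KO at E9.5 and 3.01 and 4.63 at E11.5. Within groups, the slope on this score had the sign of the stage difference for 94.2% of 172 genes with a more positive effect at E11.5, and for 76.6% of all 423 differing genes, against 66.2% of genes that did not pass. With the score as a covariate the median of the more positive differences went from 3.78 to 1.69, while its median SE went from 0.72 to 1.00, and edgeR called 0 genes. The score partly follows the groups and costs a degree of freedom, so the loss of calls also reflects lower power. For the more negative effects the share was 64.5% of 251 genes, no higher than the 66.2% of genes that did not pass. Their median went from -2.64 to -2.28 with the covariate (SE 0.48 to 0.77). The score thus gave no sign of decidua in these genes beyond that in other genes, but with so few libraries a decidual part cannot be excluded. A later demand on Tfeb at E11.5 is a hypothesis that was not tested.

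Erythroid genes had a median log2 fold change of -4.03 over 23 members at E11.5 and of -0.18 at E9.5. Dilution by decidua alone would lower all trophoblast and fetal cells alike, but the erythroid median lay below that of 22 spongiotrophoblast genes. The difference was -5.11 (one-sided permutation of genes, p = 1.0e-05, the smallest that 100000 resamples can give). The spongiotrophoblast score was 6.10 and 7.41 in wild type, with decidual scores of 2.50 and 3.53, and 8.45 and 7.95 in KO. In the E9.5 KO libraries it was 3.50, 0.28 and 1.98, with decidual scores of 4.10, 2.29 and 2.72. Libraries with more decidual RNA there also held more spongiotrophoblast RNA. The test therefore cannot decide whether an unequal share of decidua and junctional zone lowered the erythroid genes. Less fetal blood kept in the KO placentas at dissection, or held in a smaller labyrinth, cannot be told apart from fewer red blood cells made or delivered in the KO, because blood retention was not measured and the median of -4.03 would follow from either. Hba-a1 had 122959 and 78254 counts in wild type and 4677 and 6209 in KO at E11.5, and 37605, 2556 and 3454 in wild type against 27231, 3207 and 3604 in KO at E9.5, a gene picked after its values were seen.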

How the results depend on the processing

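The decidual covariate and the fits without a pair of E9.5 KO libraries were chosen after seeing the data, as were the counts of genes lower at both stages under each alternative, and the rest before. Among the named genes, 285 of 339 values at E9.5, 1420 of 1768 at E11.5, 74 of 96 for the difference between stages and 1261 of 1612 for the wild-type stages kept their direction and side of the threshold, and 16, 17, 0 and 0 changed direction. Scaling by DESeq2 size factors or the upper quartile gave 38 genes again at E9.5. The replicate block gave 46 genes at E9.5, 3502 at E11.5 and 579 for the difference. Whether replicate numbers pair the libraries stayed unsettled. At E9.5 same-number correlations were 0.49, 0.02 and 0.24, against 0.68 for wild-type library 2 with KO library 3. At E11.5 both were 0.17, which is a single value, since 2 libraries centred on their mean mirror each other. Wild-type and KO libraries 1 at E9.5 shared high mitochondrial shares (6.52% and 5.97%, against 2.55% to 3.75% in the others) and high Hba-a1 counts (37605 and 27231, against 2556 to 3604). A shared batch was not tested. The pseudocount alternative was not run, as the tables hold counts. Unless said otherwise, the cause was not tested.

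Without the filter, 123 genes passed at E9.5, 763 for the difference and 100 at both stages. DESeq2 gave 223, 1293, 3306 for the wild-type stages and 126 at both stages. All 10 libraries in one fit gave 114 at E9.5, 1023 at E11.5 and 92 at both stages, with 1 SynT-II, 5 decidual and 4 endothelial genes at E11.5. With an estimated correlation 0 lists passed in each comparison, and by fry 1, 0, 14 and 9 in the order E9.5, E11.5, difference and wild-type stages. The losses with an estimated correlation also reflect the few degrees of freedom of that test. With the decidual covariate, 0 genes passed among the E9.5 libraries, with 0 of SynT-I, and in the fit of 10 libraries 31 genes at E9.5, 3 of them of SynT-I, with 151 genes at E11.5 and 0 for the difference, with 5 SynT-I, 0 SynT-II, 4 primitive erythroid, 0 decidual, 5 nutrient transporter and 1 endothelial members at E11.5. The decidual count there tells nothing, since these members make up the covariate. Without the E9.5 KO libraries 2 and 3 a single KO library was left, and 0 genes, 0 SynT-I genes and 9 lists passed at E9.5, with 143 genes for the difference and 0 at both stages.

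Leaving out each library, which in places left a lone sample assumed to vary like the other groups, gave 0 to 325 genes at E9.5, 708 to 4468 at E11.5, 0 to 1710 for the difference, 310 to 4006 for the wild-type stages and 0 to 91 at both stages, or 36 to 37 where an E11.5 library was left out. The lists passing numbered 18 to 28, 19 to 22, 20 to 25 and 5 to 17 in the order given above. SynT-I members numbered 0 to 4 at E9.5 and 6 to 9 at E11.5, where SynT-II gave 2 to 7, primitive and definitive erythroid 9 each, decidual 6 to 12, nutrient transporters 9 to 21 and endothelium 1 to 10. The range at E9.5 was -0.45 to 0.14 for Slc16a3, -0.40 to 0.01 for Vegfa and -0.34 to 0.04 for Cdx2, and at E11.5 -0.31 to 0.01 for Tfe3, none of which passed with all libraries.

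Other reversals came with the settings for decidual RNA. With the covariate at E9.5, among the 6 and then the 10 libraries, Mitf had log2 fold changes of 0.60 and 0.94, Pparg 0.18 and 0.08, Tpbpa 1.43 and 1.28, and Ctsq 0.97 and 0.64, and without KO libraries 2 and 3 Pparg had 0.02, Tpbpa 0.49 and Ctsq 0.45. At E11.5 with the covariate Mitf had -0.55, Pparg -0.35, Tpbpa -1.23, Ctsq -1.66, Mustn1 -0.21, Trem2 -0.96, Mmp9 -1.18, Cryab -0.40, Il2rb -0.50, F13a1 -0.90, Cd68 -0.43, Csf1r -0.99, Fabp4 -2.15, Pgf -0.09, Ifi44 -0.69 and Sparc -0.39. Cryab is itself part of the decidual score. All 38 genes lower at E9.5 kept a negative value in each alternative that tested them, and 38 of them passed by DESeq2, 34 by limma-voom and 25 with the covariate among 10 libraries. Depth limits the genes of a few counts, such as Synb with 9 counts over the KO libraries at E11.5.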

Other observations

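Of the tests in this part, those of the KO placentas across stages, those on composition and on splits of the libraries, and the decidual covariate were chosen after the results were seen. Between E9.5 and E11.5 2509 genes rose and 2225 fell in the KO placentas, against 1418 and 731 in wild type. Cell cycle genes were among those lower with stage in KO, with 15 of 24 S phase and 14 of 25 mitosis genes lower, while in wild type 2 and 0 were lower by edgeR. By the test of the difference itself, 0 S phase genes and 1 mitosis gene had a more negative KO effect at E11.5 (0 and 5 adjusted over the list alone), and camera called both lists lower (adjusted p = 0.0022 and 4.0e-06), with adjusted p = 0.35 and 0.27 with an estimated correlation. The SynT-I median over 10 genes was 0.68 with stage in wild type (4 higher) and -0.04 in KO (1 higher and 4 lower). CLEAR lysosomal genes had 26 of 44 members higher with stage in KO and none lower, with a median of 0.72, against 8 higher and 2 lower in wild type, with a median of 0.27. The autophagy list had 12 of 34 members higher in KO with stage and 4 in wild type, with medians of 0.32 and 0.25. For both lists 0 genes differed in the KO effect between stages by edgeR, while camera called the CLEAR list more positive (adjusted p = 2.5e-04, and adjusted p = 0.42 with an estimated correlation). The mean decidual score in KO was 3.03 at E9.5 and 4.63 at E11.5, in the same libraries.

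Of 17 immediate early genes at E11.5, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with Fosb at 2.21 and Egr1 at 1.87, of 31 imprinted genes 12 fell and 2 rose (13 and 3 adjusted over the list alone), with Slc22a18 at -2.98 and Mest at -2.10, and of 25 mitosis genes 3 fell (2 adjusted over the list alone), Mki67, Cdc20 and Kif23 (-1.02, -0.80 and -0.73). Camera called the first list higher and the others lower (adjusted p = 0.036, 0.049 and 0.0074), with adjusted p = 0.54, 0.61 and 0.54 with an estimated correlation. Of 11 steroidogenesis genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), namely Akr1c18, which encodes an enzyme that inactivates progesterone (log2 fold change 5.68, SE 0.65, adjusted p = 6.4e-05), and Hsd3b1 (-1.51, SE 0.42, adjusted p = 0.017). Camera called the list higher (adjusted p = 0.022, and adjusted p = 0.54 with an estimated correlation). Of 8 embryo neural genes 4 fell (5 lower and 2 higher adjusted over the list alone), among them Stmn2 (-3.89) and Tubb3 (-1.33), and of 20 lipid storage genes 5 fell and 2 rose (5 and 2 adjusted over the list alone), with Cd36 at -2.61 and Fabp4 at 2.54. Camera did not call the last 2 lists (adjusted p = 0.17 and 0.073).

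Lower SynT-I expression may be an effect of Tfeb loss on this layer itself, which the tests on composition leave open as a hypothesis. At E9.5, more maternal decidua in KO would raise decidual markers, but their median was -0.58 (95% bootstrap interval -1.70 to -0.01), and less labyrinth would lower its other cells alike, but the SynT-I median lay below that of SynT-II and progenitor genes by a difference of -0.84 (one-sided permutation p = 0.0056). Only 4 of the 10 SynT-I genes passed at E9.5 and 6 did not, so this difference does not show a fall across the whole list. At E11.5 the difference from spongiotrophoblast genes, which decidua alone would dilute as well, was -3.52 (one-sided permutation p = 3.0e-05), with a spongiotrophoblast median of 1.08 (95% bootstrap interval 0.88 to 1.31). Because the spongiotrophoblast score followed the decidual score in the E9.5 KO and E11.5 wild-type libraries, this cannot decide whether more decidua and junctional zone lowered SynT-I there. These permutation p-values and bootstrap intervals resample genes that vary together, so they do not measure the spread between placentas. The 10 splits of the 6 libraries at E9.5 are too few for a share under 0.05: 1 split, the real one, gave 38 genes and the highest of the others 0. A loss of SynT-I cells, a loss of expression in cells that are present and, at E11.5, a smaller labyrinth, where the SynT-II median was -1.03, stay open.

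Genes lower in KO at E9.5 could be genes whose rise in the wild-type placenta fails or comes late. Of 37 such genes other than Tfeb, 23 were higher at E11.5 than at E9.5 in wild type, where 2.6 would be shared by chance (Fisher's exact test, p = 5.8e-18), with a median of 1.31 and 97.3% positive. The same E9.5 wild-type libraries enter both comparisons, and this acts against such an overlap, since a gene high by chance in them would seem to fall with stage. A delay and a lasting loss differ in what they predict for E11.5, where 37 of the 38 genes were still lower in KO.

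Flanking DNA of another strain, carried along with the Tfeb allele, might make genes near Tfeb differ. Within 10 Mb of Tfeb 24 of 153 genes passed at E11.5, or 15.7%, against 15.9% of genes elsewhere (one-sided Fisher's exact test, p = 0.56). This argues against flanking DNA as a source of many of the calls, but cannot exclude it for single genes. Trem2 and Vegfa, both called at E11.5, lie in this window of chromosome 17, starting at 48346401 and 46016993. At E9.5 edgeR called 0 of 152 there and 0.233% of genes elsewhere, too few for that count to tell.

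Among genes of sex chromosomes, Ddx3y had 1 count in E9.5 wild-type library 2 and 0 in E9.5 KO library 3 and E11.5 KO library 2, with 18731, 36788 and 14246 counts of Xist, whereas the other libraries had 1841 to 4350 counts of Ddx3y. The CLEAR median at E9.5 was 0.06 and -0.02 with the decidual score as a covariate among 6 and 10 libraries, whereas the interferon median was -1.43 and -1.56 and the SynT-I median -1.17 and -1.18. The mitosis median of 0.29 was 0.15 and 0.18 there and the S phase median of 0.25 was 0.16 and 0.09, by settings chosen after seeing the data.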
